A study of Mus musculus with 4 samples.

How the data were processed

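RNA was measured in 4 libraries of mouse CD4+ T cells, 2 from wild-type mice and 2 from mice lacking Pdk4, all on the C57BL/6j strain according to the labels. Per the labels' protocols, naive cells were isolated from spleen and lymph nodes with magnetic beads and kept for 48 hours with CD3, CD28 and IL-2, and each library was made from 500 ng of total RNA with the Lexogen QuantSeq kit. This kit reads the 3' ends of polyadenylated transcripts, so that a gene's count reflects the number of transcripts and not their length, and changes elsewhere in a transcript are not seen.

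The authors deposited 1 table of raw counts per library, with 1 row per gene symbol. Per the submitters' processing notes, Bowtie2, edgeR and the mm10 genome build were used, with no role or version stated. The counting tool, the gene annotation, the use of strand and the handling of reads that match several places are not given in the sources used here. Reads of near-identical genes, and of genes that overlap, may therefore have been split or assigned to 1 of them. Such genes are named as uncertain where they were recognised, and others may remain unnamed. Bowtie2 does not align reads across introns. If it was used against the genome, genes whose 3' reads cross a splice site have lower counts, in both genotypes alike. The tables hold no mitochondrially encoded genes (0 symbols of the list), so these were not analysed here. The ribosomal RNA precursor Rn45s took 12.2% and 11.6% of the counts in wild-type replicates 1 and 2, and 12.3% and 11.6% in knockout replicates 1 and 2. It was kept in the library totals, and leaving it out was tried as an alternative.

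The tables had 23282 rows and 23238 symbols. Counts of 35 symbols listed more than once were summed. Of these symbols, 15441 had at least 1 count in some library, and 11464 passed edgeR's filterByExpr and were tested. Total counts were 8837810 and 9575879 in wild type and 9739624 and 9104413 in knockout. At these depths a floor of 3 counts corresponds to between 0.308 and 0.339 CPM (here scaled to the library total alone) in a single library. Reads were not collapsed by molecular identifiers in the sources used here, so floors cover counting error only.

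Genotypes were compared with edgeR 4.0.16 in R 4.3.3 by a two-sided quasi-likelihood F test on the deposited counts, with TMM normalisation, dispersions from estimateDisp, the default settings of glmQLFit and genotype as the only term. TMM factors lay between 0.989 and 1.01. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 11464 tested genes are called changed, and "rose" and "fell" are used for these only. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are TMM-normalised CPM, given as the mean ± SD of n = 2 libraries. A gene with no count in either knockout library was given a bound against 3 counts over both knockout libraries together, which is 0.158 CPM.

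Gene lists were written from general knowledge of T cell biology before the data were examined, together with the tests, most of the alternative settings and the rule for named genes. Each list with at least 5 tested members was tested with camera in edgeR and limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 35 lists. The lists overlap in part. Each is also given with an estimated correlation, and the count of its members past the gene test is given over all genes and adjusted over the list alone. Camera with an estimated correlation draws on the few residual degrees of freedom of 4 libraries. A loss there does not by itself show that members are correlated. The lists of sex-linked genes and of neighbours of Pdk4 served as technical checks and were left out of the 35.

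The rule for named genes took Pdk4, then the 15 largest rises and the 15 largest falls among called genes with a mean of at least 10 CPM in the higher genotype and no overlap between libraries, leaving out predicted genes (Gm or Rik symbols). It also took up to 4 members of each list discussed by smallest p, the kinases Pdk1, Pdk2 and Pdk3, and Il2, Ifng, Il2ra, Cd69, Myc and Foxp3. A gene among the 15 largest falls is not reported here. Genes outside the rule are said to have been chosen after their values were seen. Positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names, matched by symbol, and 11000 of the 11464 tested genes had one.

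The test was tested on simulated data with the real genes, means and library sizes of the knockout and wild-type comparison. Each simulated gene had the dispersion of the trend at its mean, with no spread between genes around that trend. The test recovered 40.3% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 87.9% of those changed 4-fold, and 8 of 140 calls were false (5.71%). These rates need not hold for real genes that vary around the trend. A list raised in the simulation gave a camera p of 4.50e-09 and an unchanged list 0.894. The alternatives were other scalings (DESeq2's size factors, upper quartile, library size only), no filter and a stricter one, DESeq2 1.42.0, limma-voom, the likelihood ratio test, a block for the replicate number, each library left out in turn, and other thresholds. For the lists, an estimated correlation, fry and camera on voom values were tried. Positions, Fisher's exact tests and figures were made in Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.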

Results

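The series compared gene expression in activated CD4+ T cells with and without Pdk4, to ask which transcripts depend on the genotype. Pdk4 encodes a mitochondrial kinase that inhibits the pyruvate dehydrogenase complex and so limits the entry of pyruvate into the tricarboxylic acid cycle. Naive CD4+ T cells from spleen and lymph nodes were stimulated for 48 hours, and RNA was sequenced from the 3' end in 2 wild-type and 2 knockout libraries. Total counts were 8837810 and 9575879 in wild-type replicates 1 and 2, and 9739624 and 9104413 in knockout replicates 1 and 2. Between 13527 and 13763 genes had a count in each library. The labels do not tell whether replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. The counts of the libraries of a genotype were not the same, with a chi-square per degree of freedom, reads taken as independent although copies were not collapsed, of 5.40 between the wild-type and 5.45 between the knockout libraries, and of 7.89 to 10.3 between genotypes.

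Pdk4 itself (chromosome 6, 5483351 to 5496309, GRCm38) was at or under the detection floor in all libraries. It had 1 and 0 counts in wild-type replicates 1 and 2, and 0 and 2 counts in knockout replicates 1 and 2, against a floor of 3 counts, or 0.308 to 0.339 CPM. A difference was not detectable at this depth, no fold change is given, and the gene did not pass the filter for testing. The labels do not say which part of the gene was deleted, and 3' reads outside that part would persist, so these counts check nothing about the labels. The other pyruvate dehydrogenase kinases did not pass the test. Pdk1 had a log2 fold change of 0.56 (SE 0.187, adjusted p = 0.12), with 23.5 ± 3.15 CPM in wild type and 34.5 ± 5.27 in knockout (n = 2 each). Pdk3 was at 52.4 ± 1.71 and 59.6 ± 5.06 CPM (adjusted p = 0.604), and Pdk2 was low at 2.50 ± 0.645 and 1.95 ± 0.0111 CPM (adjusted p = 0.889).

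Knockout libraries had more mRNA for interleukin 2, interleukin 3 and a set of interferon-response genes, and less for B cell genes, granzyme A and the Th2 regulator Gata3. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 305 of 11464 genes changed, of which 166 rose and 139 fell in the knockout. At least 2-fold changes made up 44 of the rises and 46 of the falls. The libraries of the genotypes did not overlap in any of the 305 genes. Chance gives such separation in 1 of 3 genes with 2 libraries against 2, and 4976 of the 11464 tested genes had it. The number of called genes depended on single libraries, falling to 184 without wild-type replicate 2 and to 170 without knockout replicate 1.

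**Figure D1:**
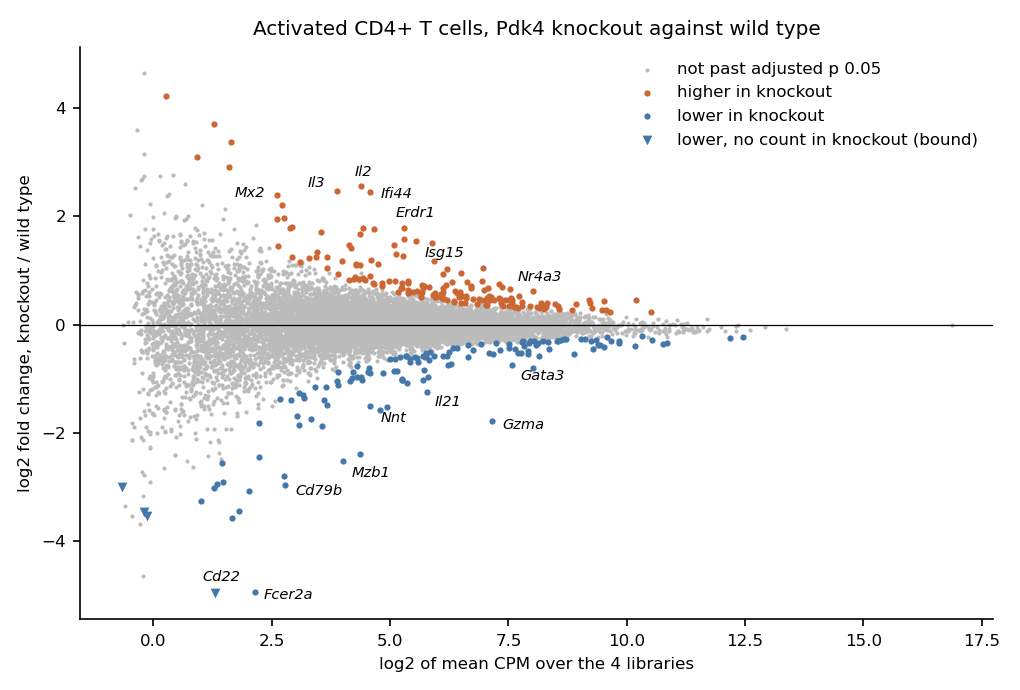
Each point is 1 of the tested genes, with the log2 of its mean CPM over the 4 libraries on the x axis and its log2 fold change, knockout over wild type, on the y axis. Orange points are the 166 genes that rose and blue points are genes that fell, among 139, with triangles at the bound for called genes that had no count in knockout, such as Cd22.

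Among the 15 largest rises of called genes that reached a mean of 10 CPM in the higher genotype, without predicted genes, Il2, the T cell growth factor, went from 6.10 ± 0.549 to 35.9 ± 5.30 CPM (n = 2 each), a log2 fold change of 2.56 (SE 0.235, adjusted p = 1.54e-08). Il3, a growth factor for myeloid progenitors, went from 4.49 ± 2.17 to 25.0 ± 6.02 CPM (2.46, SE 0.299, adjusted p = 1.14e-06). Its log2 fold change was 3.07 without wild-type replicate 2. The antiviral genes Ifi44 (2.45), Mx2 (2.40), Oas3 (1.78), Rsad2 (1.78) and Isg15 (1.55) were in this group, with Xaf1 (1.71), Ifi203 (1.77), Mndal (1.52) and Samd9l (1.98). The annotation marks Mx2 as a polymorphic pseudogene. Ifi203 and Mndal overlap on chromosome 1 and are near-identical in part, so each of these values is uncertain. The costimulatory ligand Cd70 rose by 2.22 on the log2 scale, from 2.31 ± 0.430 to 10.8 ± 1.69 CPM. The receptor Nrp1 rose from 3.37 ± 1.18 to 11.8 ± 0.0783 CPM (1.81), Tbc1d4, a regulator of glucose transporter traffic, from 19.8 ± 1.18 to 59.3 ± 7.62 (1.59), and Erdr1 from 17.6 ± 3.12 to 60.8 ± 12.9 (1.79). Erdr1 lies in a repetitive region and its value is uncertain. Samd9l was no longer called without knockout replicate 2 (adjusted p = 0.116), nor was Nrp1 without wild-type replicate 2 (0.0602).

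By the same rule, the 15 largest falls held the B cell genes Cd79b (-2.97), Mzb1 (-2.52), Fcmr (-1.75) and Pou2af1 (-1.39), and Mef2c (-2.80), a transcription factor of several lineages. Gzma, a cytotoxic granule protease, had the smallest p of all genes, falling from 219 ± 0.303 to 63.7 ± 17.6 CPM (n = 2 each, -1.78, SE 0.12, adjusted p = 7.54e-12). Others were Il24 (-1.89), Ffar2, a receptor for short-chain fatty acids (-1.85), Lmna (-1.70), Lilr4b (-1.59), Wdfy1 (-1.52), Nnt, the mitochondrial transhydrogenase (-1.50), Myo6 (-1.48) and Cysltr2 (-1.35). Lilr4b has a near-identical paralog and is uncertain. Il24 and Fcmr lie on opposite strands of chromosome 1 with their 3' ends next to each other, at 130882074 and 130880791. Their counts ran in parallel, at 139 and 204 in wild type and 55 and 41 in knockout for Il24. Fcmr had 121 and 165, and 46 and 42. As the use of strand is not given, reads of 1 may have counted for the other, and the value of Il24 is uncertain. Calls were lost without wild-type replicate 2 for Ffar2 (adjusted p = 0.0727), Lmna (0.0835), Myo6 (0.0557) and Pou2af1 (0.0558), and without knockout replicate 2 (-1.01, adjusted p = 0.193) or with DESeq2 (0.0563) for Lmna. Cysltr2 lost its call without wild-type replicate 1 (0.531), without knockout replicate 1 (0.205), with upper quartile scaling (0.0513), with DESeq2 (0.0813) and with limma-voom (0.0599). Without knockout replicate 1, the log2 fold changes of Ffar2 and Lmna were -2.60 and -3.14.

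**Figure D2:**
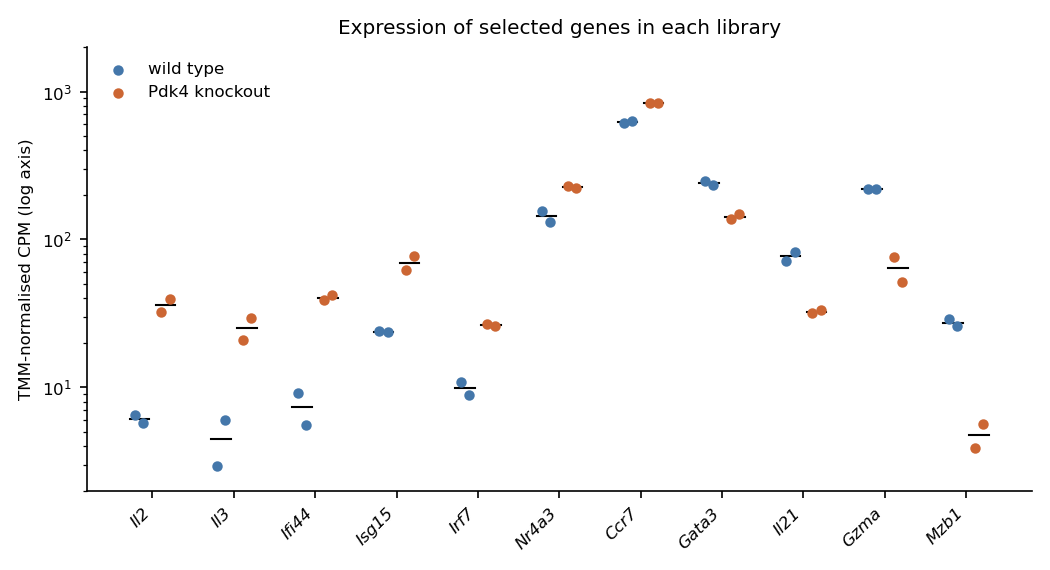
TMM-normalised CPM on a log axis for 11 genes, with 1 point per library, wild type in blue and knockout in orange, and a line at the mean of 2 libraries. In each gene shown the libraries of the genotypes do not overlap, as for Il2, with means of 6.10 CPM in wild type and 35.9 in knockout.

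Of 42 tested interferon-response genes, which type I and type II interferons induce, 14 rose, 1 fell and 27 did not pass, and 26 rose and 1 fell adjusted over the list alone. The list's median log2 fold change was 0.46, past camera's test at the preset correlation (adjusted p = 1.29e-25) and lost in 2 other tests (adjusted p = 0.177 with an estimated correlation, 0.0742 by fry). Ifi44 went from 7.41 ± 2.55 to 40.3 ± 2.07 CPM (adjusted p = 1.54e-08), Isg15 from 23.8 ± 0.229 to 69.8 ± 10.5 (2.81e-08) and Oas3 from 9.62 ± 0.740 to 33.2 ± 2.13 (1.30e-06). The member that fell was Ly6e (-0.33), chosen after its values were seen. In the same libraries 15 of 18 B cell markers and 4 of 18 CD8 T and NK cell markers fell, with median log2 fold changes of -2.42 and -0.89. Without knockout replicate 1, 9 members rose. Ly6e was not called without knockout replicate 1 or wild-type replicate 2, when 0 members fell.

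Cytokine and chemokine genes moved both ways, with 6 of 26 tested members rising and 2 falling (7 and 3 adjusted over the list alone). In the same libraries 15 of 18 B cell markers, 4 of 18 CD8 T and NK cell markers and 2 of 5 innate-like markers fell. Besides Il2 and Il3, the rises included the chemokine Ccl5, from 14.7 ± 0.452 to 33.5 ± 1.73 CPM (1.19, adjusted p = 0.000226), and Ccl4, from 13.2 ± 1.69 to 28.2 ± 1.89 (1.09, 0.00212). Il21, a cytokine of follicular helper and Th17 cells, fell from 77.0 ± 8.17 to 32.5 ± 0.907 CPM (-1.24, adjusted p = 3.64e-07). Il24, whose value is uncertain as stated above, fell from 18.7 ± 4.07 to 5.04 ± 0.823 (-1.89). The list had a median of 0.23 (adjusted p = 0.000531 by camera, and adjusted p = 0.2 with an estimated correlation). Its median was 0.59 without wild-type replicate 2 and 0.10 with no filter, and the list was not called without wild-type replicate 1 (adjusted p = 0.0756). Without knockout replicate 2, 4 members rose.

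Among helper subset lists, the Th2 list passed camera's test downward and the Th1 list upward at the preset correlation (adjusted p = 2.37e-06 and 0.000824), which was lost for both (adjusted p = 0.184 and 0.253 with an estimated correlation, 0.0742 and 0.139 by fry). In the same libraries 15 of 18 markers of B cells, 4 of 18 of CD8 T and NK cells and 2 of 5 of innate-like T cells fell, the last including Maf, which the Th2 list shares, and the medians were -2.42, -0.89 and -1.16. Of 11 tested Th2 genes, 3 fell and 8 did not pass (4 fell adjusted over the list alone), with a median of -0.71. Gata3, the lineage-defining factor of Th2 cells, went from 241 ± 8.47 to 143 ± 7.23 CPM (-0.76, SE 0.0888, adjusted p = 7.50e-07), and the others were Il24, whose value is uncertain, and Maf (-1.16). Of 14 Th1 genes, Ccl5, Ccl4 and Lta (0.46) rose (3 in all, and 4 rose and 1 fell adjusted over the list alone), with a median of 0.32. Ifng, the main Th1 cytokine, was at 13.6 ± 2.63 and 7.63 ± 0.485 CPM and did not pass (-0.83, adjusted p = 0.155). The Th2 median was -0.25 with the stricter filter and -0.26 without wild-type replicate 2, where 2 members fell as they did without knockout replicate 1. The Th1 median was 0.16 without wild-type replicate 1, 0.18 without knockout replicate 1 and 0.13 without knockout replicate 2. Maf was not called without knockout replicate 1 (adjusted p = 0.257) or wild-type replicate 2 (0.211) or with DESeq2 (0.0679), nor Lta without wild-type replicate 1 (0.258) or knockout replicate 2 (0.17) or with DESeq2 (0.527), which left 2 Th1 rises, and the log2 fold change of Lta was 0.25 without wild-type replicate 1 and 0.70 without wild-type replicate 2. The lists for Th17 (0 rose and 2 fell of 8, adjusted p = 0.11), Treg (1 and 1 of 18, 0.625) and Tfh cells (1 and 1 of 10, 0.966) did not pass. The genes that changed were Il21 and Irf4 (-0.31) in the Th17 list, Nrp1 and Tnfrsf9 (-0.29) in the Treg list, and Slamf6 (1.46) and Il21 in the Tfh list. Without wild-type replicate 2, Nrp1 (0.0602), Tnfrsf9 (0.0608) and Slamf6 (0.329) were not called, nor were Irf4 (0.177), Tnfrsf9 (0.299) and Slamf6 (0.325) without knockout replicate 1 or Slamf6 without knockout replicate 2 (0.0698). Slamf6 was also lost with the other 3 scalings (0.0531 for DESeq2's size factors, 0.0741 for upper quartile and 0.0520 for library size only), DESeq2 (0.106) and limma-voom (0.0614). Adjusted over the list alone, 1 and 3, 1 and 2, and 3 and 2 of their members rose and fell. The Th17 list passed with the stricter filter (0.00817). The Th17 median was 0.08 and its mean 0.11 although camera gave a downward direction. The Treg mean was 0.05 and its median -0.04. Foxp3 was at 28.0 ± 4.78 and 20.5 ± 5.66 CPM (adjusted p = 0.351).

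The calcium and NFAT signalling list holds components of the pathway as well as genes that it induces. Of its 20 tested members 4 rose, with 0 falls and 16 not past the test (4 rose and 1 fell adjusted over the list alone). In the same libraries 15 of 18 B cell markers, 4 of 18 CD8 T and NK cell markers and 2 of 5 innate-like markers fell. Of the calcium and NFAT genes, those that rose were the immediate-early nuclear receptors Nr4a3, from 144 ± 18.5 to 226 ± 6.05 CPM (0.65, adjusted p = 2.25e-05), Nr4a2, from 58.1 ± 5.28 to 99.9 ± 5.75 (0.78, 6.67e-05), and Nr4a1 (0.46), with Egr3 (0.68). Camera gave adjusted p = 0.00207 for the list, and adjusted p = 0.234 with an estimated correlation. Nr4a1 and Egr3 were not called without wild-type replicate 2 (adjusted p = 0.142 and 0.109) or knockout replicate 2 (0.118 and 0.119), leaving 2 rises in each case. The general T cell activation list did not pass (3 rose and 2 fell of 23, adjusted p = 0.0591, with 7 and 6 adjusted over the list alone), except with library size only (0.0396), without wild-type replicate 2 (0.0452) and without knockout replicate 1 (0.016). Its risers were Il2, Nr4a1 and Cd44 (0.48), the last chosen after its values were seen, and Irf4 (-0.31) and Tnfrsf9 (-0.29) fell. In this list 1 gene rose and 1 fell without wild-type replicate 2, and 2 rose and 0 fell without knockout replicate 1. Irf4 was lost without the latter (adjusted p = 0.177), as was Tnfrsf9 (0.299), which was also lost without wild-type replicate 2 (0.0608). Il2ra was at 1200 ± 37.1 and 1035 ± 38.9 CPM (adjusted p = 0.0557, and under 0.05 in 8 of 16 alternatives, among them 0.0303 with DESeq2 and 0.0146 with limma-voom), Cd69 at 79.0 ± 8.45 and 102 ± 0.531 (0.0832), and Myc at 19.1 ± 0.370 and 22.9 ± 6.30 (0.681). In the resting T cell list, 4 genes rose and 1 fell of 20 (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.49). The lymph node homing receptor Ccr7 rose from 624 ± 11.7 to 839 ± 3.25 CPM (0.43), and the chromatin organiser Satb1 fell from 1949 ± 66.0 to 1524 ± 112 (-0.36). Satb1 was not called without knockout replicate 1 (0.0555). Without wild-type replicate 2 or knockout replicate 1, 1 resting gene rose, and 2 rose without knockout replicate 2.

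Metabolic lists, which hold the pathway that Pdk4 acts on, showed small shifts. Among the 13 genes of pyruvate oxidation, 0 rose and 0 fell, with a median of -0.06, or -0.147 to 0.0172 over the alternatives (adjusted p = 0.646 by camera). The count was 0 also adjusted over the list alone, with DESeq2 and with limma-voom, and 1 gene, Pdk1, had an unadjusted p under 0.05 in edgeR. Of 18 genes of the tricarboxylic acid cycle, Mdh1 fell (-0.37) and 17 did not pass (adjusted p = 0.325, with 1 fall adjusted over the list alone). Glycolysis genes had a median of -0.18, and 2 of 19 fell (5 adjusted over the list alone), namely Aldoa, from 904 ± 77.4 to 732 ± 47.7 CPM (-0.30), and Pkm, from 721 ± 73.5 to 595 ± 15.1 (-0.28). Respiratory chain genes encoded in the nucleus had a median of -0.10, and 4 of 72 fell (5 adjusted over the list alone), including Ndufv3, from 188 ± 2.66 to 135 ± 9.90 CPM (-0.48). Camera gave adjusted p = 0.000403 for glycolysis and 7.96e-05 for the respiratory chain, and adjusted p = 0.398 and 0.184 with an estimated correlation. Without wild-type replicate 2 or knockout replicate 1, 0 glycolysis genes fell, with adjusted p of 0.19 and 0.262 for Aldoa and of 0.411 and 0.12 for Pkm, which was also lost without knockout replicate 2 (0.206), when 1 fell. The log2 fold change of Pkm was -0.17 without wild-type replicate 2. Only 1 respiratory chain gene fell without wild-type replicate 2, knockout replicate 1 or knockout replicate 2, and Ndufv3 was lost without the last (0.0654). Mdh1 lost its call without any 1 of the libraries (adjusted p = 0.0551 without wild-type replicate 1, 0.284 without wild-type replicate 2, 0.32 without knockout replicate 1 and 0.105 without knockout replicate 2), with library size only (0.0692) and with DESeq2 (0.0659).

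Fatty acid and cholesterol synthesis genes had a median of -0.14 with 0 of 26 past the gene test (2 fell adjusted over the list alone, and Acly passed in 3 of 16 alternatives), and camera gave adjusted p = 0.00375, or adjusted p = 0.253 with an estimated correlation. That list was not called without wild-type replicate 2 (0.0686), and its median was -0.22 without knockout replicate 2. In the lists for fatty acid oxidation (21 genes, adjusted p = 0.66), contacts between endoplasmic reticulum and mitochondria with mitochondrial calcium (26, 0.646), and mitochondrial dynamics (17, 0.947), 0 genes passed, also adjusted over the list alone. DESeq2 and limma-voom also called 0 genes in these 4 lists, and 1 gene of the contact list rose without wild-type replicate 1. At an unadjusted p under 0.05, edgeR's test had 6 genes of fatty acid and cholesterol synthesis, 2 of fatty acid oxidation, 7 of the contact list and 2 of mitochondrial dynamics.

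Growth-related lists had medians of either sign, and the lists were not tested against each other. Targets of MYC and genes of ribosome biogenesis had a median of 0.14, and 4 of 39 rose with 0 falls (5 rises adjusted over the list alone), among them Ppan, from 39.5 ± 1.59 to 65.0 ± 2.07 CPM (0.72, adjusted p = 0.00142). Ribosomal protein genes had a median of -0.10, with 0 of 78 past edgeR's gene test, also adjusted over the list alone. DESeq2 called 0 and limma-voom 4 of them, and 22 had an unadjusted p under 0.05 in edgeR. Rps24 and Rps27 (adjusted p = 0.0564 and 0.0547) passed in 7 and 6 of 16 alternatives. Camera gave adjusted p = 1.68e-06 and 5.48e-07, and adjusted p = 0.184 and 0.398 with an estimated correlation. Genes of the ATF4 amino acid response had a median of 0.08, and 4 of 36 rose (5 adjusted over the list alone), including Asns, the asparagine synthetase, from 173 ± 9.23 to 248 ± 5.74 CPM (0.52, adjusted p = 0.000189). Asns also lies near Pdk4 on chromosome 6. This list had adjusted p = 0.000605 by camera and adjusted p = 0.2 with an estimated correlation. Leaving out any 1 library left 2 MYC or ribosome biogenesis genes that rose, and 2 of the ATF4 genes without wild-type replicate 1, knockout replicate 1 or knockout replicate 2. Without wild-type replicate 1, 9 ribosomal protein genes fell, and 1 without knockout replicate 2.

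Cell cycle and stress lists changed little. Genes of the G2 and M phases had a median of -0.13, and Mki67 (-0.33) was the 1 of 41 that fell, also adjusted over the list alone (adjusted p = 0.00374 by camera, and adjusted p = 0.398 with an estimated correlation). The list's median was -0.08 without knockout replicate 2 (0.0645), and Mki67 lost its call without any 1 of the libraries (adjusted p = 0.0748 and 0.0796 without wild-type replicates 1 and 2, 0.143 and 0.153 without knockout replicates 1 and 2). S phase genes (0 of 39, adjusted p = 0.585), p53 targets (0 of 19, 0.646) and NRF2 targets (0 of 21, 0.751) had 0 calls in edgeR, also adjusted over the list alone, and 0 in DESeq2 and limma-voom, with 4, 2 and 3 genes at an unadjusted p under 0.05. Without wild-type replicate 1, 1 S phase gene rose and 1 NRF2 target fell. In the apoptosis list, 3 of 28 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.55). The rises were the survival genes Bcl2a1d (0.79), Bcl2a1b (0.67) and Bcl2l1, from 156 ± 1.91 to 219 ± 1.33 CPM (0.49), and Casp6 fell (-0.91), except without wild-type replicate 2 (0.204). Bcl2a1b and Bcl2a1d are near-identical and uncertain.

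Most B cell markers, and a part of the markers of other lymphocytes, fell in the knockout libraries. Of 18 tested B cell markers, 15 fell and 3 did not pass (16 fell adjusted over the list alone), with a median of -2.42, or -1.79 with the stricter filter. Fcer2a went from 8.62 ± 0.835 to 0.269 ± 0.235 CPM (-4.96, adjusted p = 6.76e-06), with log2 fold changes of -4.27 and -6.22 without knockout replicates 1 and 2. Cd22 had 36 and 55 counts in wild type and 0 and 0 in knockout, at least 31.3-fold lower, and the median was -2.42 also with Cd22 at this bound. Of 18 CD8 T and NK cell markers, 4 fell (8 adjusted over the list alone), with a median of -0.89, or -0.31 with the stricter filter. Apart from Gzma these were Fcer1g (-1.12), Gzmc (-0.91) and Klrc1 (-0.89). Of 5 markers of γδ, NKT and innate-like T cells, Gzma and Maf fell (2, and 3 adjusted over the list alone), with a median of -1.16. Camera gave adjusted p = 1.52e-36, 4.47e-13 and 2.90e-10 for these lists, and adjusted p = 0.177, 0.177 and 0.184 with an estimated correlation. The T cell genes Cd4 (253 ± 2.13 and 260 ± 13.0 CPM) and Cd3e (67.3 ± 0.695 and 69.9 ± 7.84), chosen after their values were seen, were not called.

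The B cell markers that fell numbered 6 without wild-type replicate 2 and 8 without knockout replicate 2. Without wild-type replicate 2 or knockout replicate 1, 2 CD8 T and NK cell markers and 1 innate-like marker fell, and without the latter the innate-like median was -2.10. Calls were lost for Fcer1g without knockout replicate 1 (adjusted p = 0.121), for Gzmc without wild-type replicate 2 (0.335) and knockout replicate 2 (0.0698), and for Klrc1 without wild-type replicate 2 (0.227) and knockout replicate 1 (0.254). Myeloid markers did not pass (1 of 12, Fcer1g, fell, with 1 rise and 2 falls adjusted over the list alone, adjusted p = 0.179, or 0.0182 and downward without knockout replicate 2). The erythroid and platelet list passed at a median of 0.46 with 0 of 8 genes called, also adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.628 with an estimated correlation). Its call was also lost with the other 3 scalings (0.0524 for DESeq2's size factors, 0.0639 for upper quartile and 0.0771 for library size only), no filter (0.0839), the stricter filter (0.0562) and fry (0.772), and held in 5 of 15 alternatives. It had medians of 1.88 without wild-type replicate 1, when 6 genes rose, 0.95 without knockout replicate 1, -0.26 without wild-type replicate 2 and -0.40 without knockout replicate 2. Of 3 stromal markers measured, 0 passed over all genes, and 1, Col1a2, adjusted over the list alone. Sex-linked genes did not differ by the test (0 of 5), with the Y-linked Ddx3y at 100.2 ± 1.93 and 95.6 ± 1.89 CPM.

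**Figure D3:**
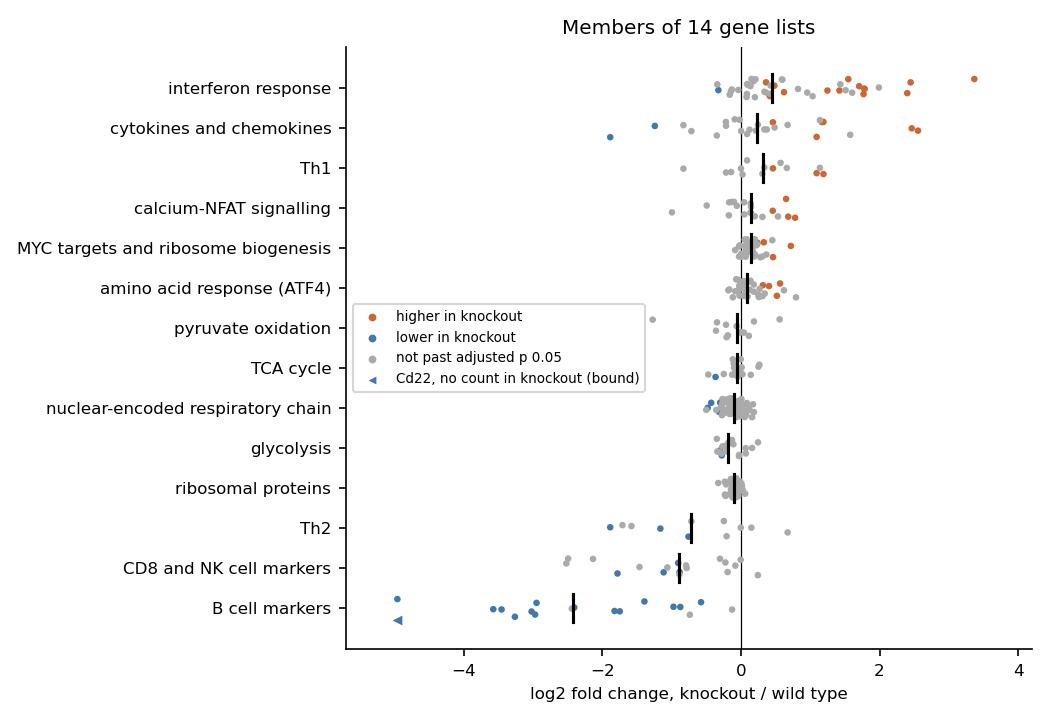
The x axis is the log2 fold change, knockout over wild type, of each tested member (points) of 14 gene lists (rows), with a black bar at the list's median. Orange and blue points rose and fell, grey points did not pass, and medians run from -2.42 for B cell markers, where the triangle marks Cd22 at its bound, to 0.46 for interferon-response genes.

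Over the 35 lists, 16 passed at the preset correlation, 7 upward and 9 downward, against 0 with an estimated correlation, where 8 had an unadjusted p under 0.05. The latter form has few residual degrees of freedom with 4 libraries, which raises its p-values. For B cell markers the estimated correlation was -0.00464, below the preset 0.01, yet camera's unadjusted p went from 4.35e-38 to 0.00506. A call lost in this form therefore does not by itself show that correlated members made it. Estimated correlations differed between the lists that lost their call. They were 0.205 for ribosomal proteins, 0.216 for glycolysis and 0.837 for erythroid and platelet markers, but -0.0370 for calcium and NFAT signalling. Where the estimate was well above the preset value, correlated members may have added to the loss. By fry, which tests whether the genes of a list move on balance 1 way, 6 passed, those of B cell, CD8 T and NK cell, and innate-like markers, calcium and NFAT signalling, the respiratory chain, and MYC targets and ribosome biogenesis. Not counting genes of the lists for other cell types, chosen as an alternative after seeing the data, 285 genes changed, of which 166 rose and 119 fell.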

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

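Settings without the ribosomal precursor Rn45s, without repeated symbols, without counting genes of other cell types, and with bias-adjusted quasi-likelihood were chosen after seeing the data. Under other scalings, filters and tests, the count of 305 changed genes ranged from 235 (DESeq2) to 377 (no filter), with 290 for DESeq2's size factors, 250 for upper quartile (125 higher and 125 lower), 284 for library size only (172 higher, or 60.6%, against 54.4%), 365 for a stricter filter, 322 for limma-voom, 362 for the likelihood ratio test and 341 for the bias-adjusted fit. It was 304 without Rn45s, 304 without repeated symbols, 285 without genes of other cell types, 442 at an adjusted p under 0.1, and 90 with a 2-fold minimum, which is stricter by construction. Of the 305 genes, 0 changed sign in these settings. Leaving out 1 library gave 170 to 293 changed genes, 92 to 148 higher, 75 to 145 lower and 15 to 17 lists. Such fits have fewer samples and assume that the lone library varies like the pair. The number of lists past the test, 16, fell to 0 with an estimated correlation and to 6 with fry, and was 15 to 17 otherwise. With only 2 libraries per genotype, the simulated 1.5-fold changes were recovered in 40.3% of cases, so many small changes would be missed.

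With a replicate block, 260 genes changed (142 higher, 118 lower), 256 of them among the 305, and among named calls those of Cysltr2, Mdh1, Ndufc1, Slamf6, Slc6a9, Higd1a, Peg10 and the erythroid and platelet list were lost. Deviations of same-numbered libraries had a correlation of 0.0111 across genes, and the labels do not say what a number marks, so the numbers were not taken to pair the libraries. The planned older quasi-likelihood fit is this version's default and so identical to the fit reported. Leaving out mitochondrially encoded genes was not run, as the tables hold 0 of them, and no fold change is given for Pdk4 under any setting. Over named genes that were called, 1270 gene and setting pairs stayed called and 134 lost the call, and over called lists 202 stayed, 35 lost it and 2 lost it and reversed. Outside the calls, 44 gene and 7 list pairs gained one.

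Directions reversed as follows, taken from the log2 fold change for genes and from camera's direction for lists, and the cause was not tested. Medians of lists whose camera direction held could also change sign over the alternatives. They ranged from -0.147 to 0.0172 for pyruvate oxidation, -0.0421 to 0.161 for T cell activation and -0.0525 to 0.0439 for resting T cells. For inhibitory receptors they ranged from -0.203 to 0.299, for Th17 from -0.181 to 0.148 and for apoptosis from -0.0323 to 0.0953. With the stricter filter the Tfh list's camera direction turned, at a median of 0.136, and that of PPAR and FOXO targets at -0.0475. Over the fits without 1 library, log2 fold changes of uncalled genes ranged from -0.0517 to 0.517 for Myc, -0.0139 to 0.25 for Hadha, -0.397 to 3.08 for Hba-a2, -0.357 to 1.96 for Hbb-bt, -0.402 to 1.94 for Hbb-b2, -0.0879 to 0.636 for Entpd4, -0.343 to 0.128 for Cd74, -0.0149 to 0.087 for Cd4 and -0.0649 to 0.164 for Cd3e. List medians ranged from 0.0147 to 0.0997 for contacts between endoplasmic reticulum and mitochondria, -0.0656 to 0.0643 for mitochondrial dynamics, -0.221 to 0.0800 for Treg, 0.0153 to 0.337 for Tfh, -0.0643 to 0.0238 for S phase, -0.0733 to 0.0361 for p53, -0.0765 to 0.0733 for NRF2, -0.0561 to 0.0548 for PPAR and FOXO targets, and -0.397 to 1.88 for erythroid and platelet markers. The last was the only called list to reverse, and its hemoglobin genes varied widely between libraries.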

Other observations

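The tests of other splits, of fewer B cells and of transcripts brought by other cell types were chosen only after the results were seen, and the last tests were revised with the values in view. Also chosen after the results were seen were the genes Id2, Id3, Rbpj, Lad1, Amica1, Il23a, Cd2, Cd52, Ly6a, Ly6c1, Ide, Entpd4 and Cd74.

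Several transcriptional regulators and surface genes outside the lists differed between genotypes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The inhibitors of DNA binding moved apart, with Id3 rising from 17.0 ± 1.11 to 37.0 ± 1.92 CPM (1.12, adjusted p = 0.000236) and Id2 falling from 256 ± 2.43 to 179 ± 5.08 (-0.52, adjusted p = 0.000136). Rbpj, the DNA-binding partner of Notch, fell from 330 ± 14.4 to 189 ± 13.1 CPM (-0.80, adjusted p = 6.56e-08). Lad1 rose from 81.5 ± 1.90 to 169 ± 1.30 CPM, Il23a, a subunit of interleukin 23, from 48.6 ± 0.119 to 99.3 ± 3.24, and the adhesion gene Amica1 from 18.0 ± 2.16 to 50.1 ± 6.30. The surface genes Cd2 (-0.41), Cd52 (-0.55), Ly6a (-0.40) and Ly6c1 (-0.60) fell, and Ly6c1 was not called without wild-type replicate 2 (-0.35, adjusted p = 0.305). Among 356 families of genes that share a symbol stem, the Cd stem, which names surface antigens, had 4 of 61 members rising and 5 falling, and the Ly stem had 4 of 10 members falling, Ly6a, Ly6c1, Ly6d and Ly6e (Fisher's exact test, one-sided, adjusted p = 0.0109 and 0.0162). Of these, Ly6d is a B cell marker, and Ly6c1 and Ly6e were not called without wild-type replicate 2.

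Lists for inhibitory receptors (1 rose of 11, adjusted p = 0.172 by camera), the unfolded protein response (1 fell of 24, 0.11), the hypoxia response (1 rose and 2 fell of 24, 0.191) and PPAR and FOXO targets (1 rose of 17, 0.966) did not pass. With the stricter filter the receptor (0.0109) and unfolded protein (0.0477) lists passed. Adjusted over the list alone, 2 rose, 1 rose and 2 fell, 2 rose and 5 fell, and 2 rose. The receptor list's riser was Nr4a2, a nuclear receptor, and that of the FOXO list was Ccr7. Hsp90b1, an endoplasmic reticulum chaperone (-0.27), was not called without any 1 of the libraries (adjusted p = 0.155, 0.0648, 0.171 and 0.256 without wild-type replicates 1 and 2 and knockout replicates 1 and 2), with library size only (0.0667) or by the likelihood ratio test (0.0501). In the hypoxia list Ndrg1 rose (0.54), and Hif1a (-0.28) and Higd1a (-0.39) fell. Ndrg1 was not called without wild-type replicate 1 (0.0829), wild-type replicate 2 (0.0882) or knockout replicate 2 (0.232), Hif1a without wild-type replicate 2 (0.271), knockout replicate 1 (0.221) or knockout replicate 2 (0.132), and Higd1a without any 1 of the libraries (0.0776, 0.265, 0.231 and 0.168 in the order above), with library size only (0.0687) or with DESeq2 (0.0679).

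The 4 libraries can be split into pairs in 3 ways. The genotype split called 305 genes and the highest of the others 0 by edgeR's test, with 220 and 213 genes at an unadjusted p under 0.05 against 1545, so 1 split of 3 reached the real count. With 3 splits the share cannot fall under 0.05.

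B cell transcripts were lower in the knockout libraries, at a list median of -2.42. The choice of scaling is argued against as the cause, since the highest median under the other 3 scalings was -2.40. Under those scalings the median log2 fold change of all genes lay between -0.0110 and 0.0223. They could therefore not have removed a fall of this size. Fewer B cells passing the bead isolation in the knockout samples may be a cause, and 66.7% of members with at least 5 CPM in wild type (8 of 12) lay below a log2 fold change of -1. The 4 exceptions were H2-Aa, H2-Ab1, H2-Eb1 and Cd74, the last at 103 ± 23.6 and 94.0 ± 9.87 CPM, which dendritic and other antigen-presenting cells also express, so this value leaves fewer B cells and a change within cells open. An effect of Pdk4 on B cells or on how they survive the culture is equally open and was not tested.

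Of 42 interferon-response genes 14 rose and 1 fell in the knockout, a list not called with an estimated correlation (adjusted p = 0.177). A chromosome segment carried over with the knockout allele and acting in cis is argued against, as the 14 members that rose lie on 12 chromosomes, which leaves a regulator carried on such a segment open. A larger share of B, CD8, NK or innate-like T cells in the knockout cultures is argued against, since the highest median of their lists over all settings was -0.31. The rule for these lists was written with their falls in view, and it asked less of them than of the myeloid list. Higher expression of interferon-response genes within such cells was not tested. More erythroid cells are argued against too, as 0 of 7 erythroid markers were higher in both knockout libraries than in both wild-type libraries. So is the choice of scaling, with a lowest interferon median of 0.44 under the other 3 scalings, which shifted all genes only slightly. Myeloid cells stay open, as the median of their list was -0.0878 over members that went both ways (4 positive and 8 negative). That median ranged from -0.898 to -0.0666 over the alternatives, and the bead isolation of naive CD4+ T cells is meant to remove such cells. Platelets and stromal cells were not tested as carriers and stay open as well. The platelet marker Itga2b was at 2.15 ± 0.344 CPM in wild type and 3.79 ± 0.132 in knockout, and was not called. Of the 3 stromal markers, 1 had a positive and 2 a negative log2 fold change, and 0 were called. Loss of Pdk4, an environment shared by the knockout mice or cultures and a substrain difference are further hypotheses that stay open, and the design does not separate them.

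Nnt and Wdfy1 fell and Ide rose in the knockout, Ide from 37.7 ± 2.03 to 85.0 ± 9.99 CPM (1.17, adjusted p = 5.28e-07). From general knowledge, these genes differ between C57BL/6 substrains, as does Entpd4, so a substrain difference between the mice of the genotypes may be a cause. Entpd4 had a log2 fold change of 0.32 (adjusted p = 0.597), and -0.0879 without knockout replicate 2, which is too imprecise to separate this from an effect of Pdk4. A segment carried over around Pdk4 is argued against for these genes, as 0 of the 3 lie within 10 Mb of it (chromosomes 13, 1 and 19 for Nnt, Wdfy1 and Ide). Within that distance 3 of 21 tested genes were called (14.3%), against 291 of 10979 elsewhere (2.65%; Fisher's exact test, two-sided, p = 0.0176). These were Asns, Samd9l and Peg10, the last at least 7.99-fold lower, with 12 and 11 counts in wild type and 0 and 0 in knockout, and Peg10 was not called without knockout replicate 1 (0.381) or 2 (0.287), with the other 3 scalings (0.0542 for DESeq2's size factors, 0.0677 for upper quartile and 0.0581 for library size only), no filter (0.173), DESeq2 (0.103) or the bias-adjusted fit (0.0967). Samd9l was lost without knockout replicate 2 (0.116), so the test of this share rests on calls that depend on the setting. Of the 17 tested genes of the fixed neighbour list, Asns rose and Peg10 fell.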
